A study of Homo sapiens with 12 samples.

How the data were processed

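RNA was measured by sequencing in 12 libraries of MDA-MB-231, an established human line of triple-negative breast cancer grown as adherent cells. Per the labels, the libraries fall into 4 groups of 3: untreated cells, cells given TGFβ, cells given alisertib, and cells given both, with 48 h of treatment. TGFβ is a secreted growth factor that signals through SMAD proteins. Alisertib is a small-molecule inhibitor of the mitotic kinase Aurora A. Doses were not given in the sources used here. The replicate numbers run through the whole series and are not shared between groups, so libraries were not paired. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries and that spread can be technical.

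Per the labels' protocols, total RNA was extracted with the miRNeasy kit and libraries were made with a TruSeq RNA v2 kit, which does not mark the strand. Reads of overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies can share reads. Per the submitters' processing notes, bcl2fastq, TopHat, Subread and featureCounts were used with the build hg19. Their versions, settings and gene annotation were not given in the sources used here. The deposited table holds whole-number read counts per gene, made by the authors without normalisation, for 57773 genes. It also holds RPKM values that the authors computed from those counts. The RPKM values served only to check the authors' scaling: their denominators were 1.1 to 1.11 times the total count of the same library. Coordinates are those of the file, in hg19. Gene lengths were those of the deposited table. A newer annotation was used only for current gene symbols and GC content. It gave a current symbol for 19518 of the 20571 tested genes and a GC content for 19649.

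Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 20571, and libraries were scaled by TMM factors. All 12 libraries entered 1 quasi-likelihood fit with robust dispersion estimates and 8 residual degrees of freedom. The tests were the 5 pairwise comparisons and the interaction, which is the alisertib effect with TGFβ minus the alisertib effect without it. Adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the tested genes, and a gene was called changed at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM, read counts scaled to a common library size with TMM factors, as mean ± SD over 3 libraries.

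Altogether 29 gene lists with 604 members were written before the data were examined, as were the groups, the tests, the other settings to be tried and the rule for naming genes. Of the members 544 were tested. Among the lists were markers of leukocytes, endothelial cells and luminal breast cells, cell types other than the one the labels name, and mitochondrial transcripts. A list needed 5 tested members, which the endothelial list did not reach with 4, so 28 lists were tested. Lists were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, and p-values were adjusted over the lists of a comparison. The alternatives were camera with a correlation estimated from the data, and fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes. The lists are the present author's choice from textbook knowledge, and none was chosen on these libraries.

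The genes named are, per comparison, the 6 highest and 6 lowest changes among called genes with a mean of at least 5 CPM and no overlap between the groups' values, up to 4 members of each list past its test and up to 2 of each other list, and 12 fixed genes of the TGFβ response, the epithelial, mesenchymal and stem-like states and the Aurora kinases, of which 10 were tested. Clone-based and non-coding symbols were left out of the extremes. For the interaction they are the 4 highest and 4 lowest, without the condition on overlap. Genes outside this rule are named as such, and some genes within it are not reported here.

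The fit was tested on simulated data, with known fold changes set in 200 genes and the list of DNA replication genes lowered. Counts were drawn for the real genes from their means in untreated libraries and the real library sizes. Genes were drawn independently, without the deviation along GC content that the real libraries shared. False calls of genes and lists can therefore be more frequent in the real data than in the simulation. In the simulated comparison of alisertib with untreated cells over 19841 genes, 6% of changes of 0.25 on the log2 scale were recovered, 42% of 0.5, 66% of 1 and 88% of 2, with 6 false calls. In the simulated interaction over 19832 genes the recovered shares were 0%, 32%, 58% and 84%, with 3 false calls. False calls were most numerous for TGFβ with alisertib, at 10 (8.547% of the calls). Among lists that were not lowered, camera called 3 for both agents against untreated cells. It called 1 for TGFβ against untreated cells and 1 for TGFβ with alisertib, and 0 in the other comparisons. Most changes of 0.25 were not detectable in these simulated comparisons at this depth and spread. Total counts were 93701658 to 120619368 per library.

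The other settings chosen then were size factors of the DESeq2 kind, upper-quartile factors, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, and leaving out each library in turn. After the data were seen, 3 more were added: an offset per library from a spline in GC content and gene length, a fit of 8 libraries without the 4 that deviated together, and the leading component of the within-group deviations as a covariate. No library was left out of the reported fit, and no sample column was left unmapped.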

Results

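Transcript levels were measured in 12 libraries of MDA-MB-231 cells: 3 untreated, 3 treated with TGFβ, 3 treated with alisertib and 3 treated with both. The design asks how each agent changes expression and whether the response to 1 agent depends on the other. Total counts per library were 93701658 to 100328721 in untreated cells, 110282980 to 118220032 with TGFβ, 97048328 to 105563951 with alisertib and 105921831 to 120619368 with both. Mitochondrial transcripts took 3.217% to 3.856% of the counts of a library, and 20571 genes were tested.

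TGFβ treatment separated the libraries along the first principal component, which held 59.6% of the variance. The second component held 8.23%, with scores of 7.1 to 28 in libraries with alisertib and -31.9 to 0.1 in those without. Within each group 1 library stood apart from its partners: untreated library 1, TGFβ library 6, alisertib library 9 and combined library 10. Their deviations correlated with each other across 11717 genes at 0.701 to 0.856. In these 4 libraries the deviation from the group mean fell with the GC content of the gene, with a Spearman rho across genes of -0.726, -0.747, -0.717 and -0.78. Genes are not independent replicates, so these values describe the libraries only.

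**Figure D1:**
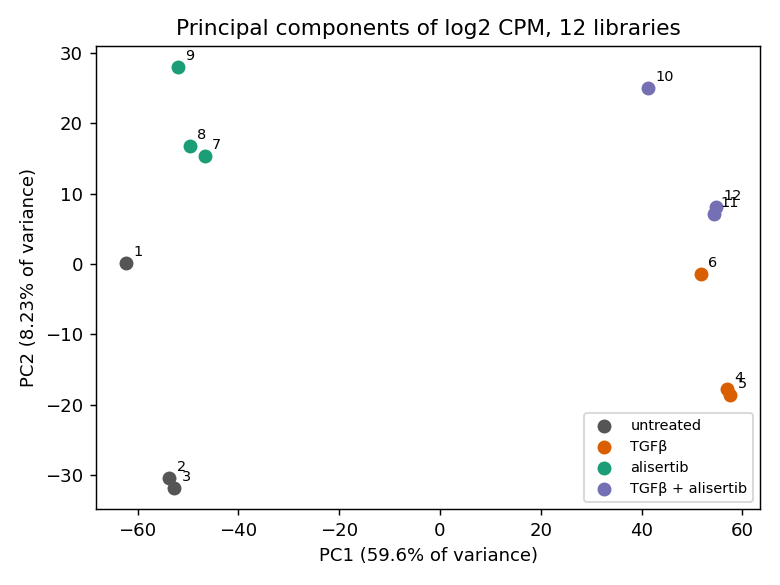
Scores of the 12 libraries on the first and second principal components of log2 CPM, with 59.6% and 8.23% of the variance; points are libraries, colours are groups and numbers are replicate numbers. Libraries with TGFβ lie at 41.3 to 57.6 on the first component and those without at -62.3 to -46.6.

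**Figure D2:**
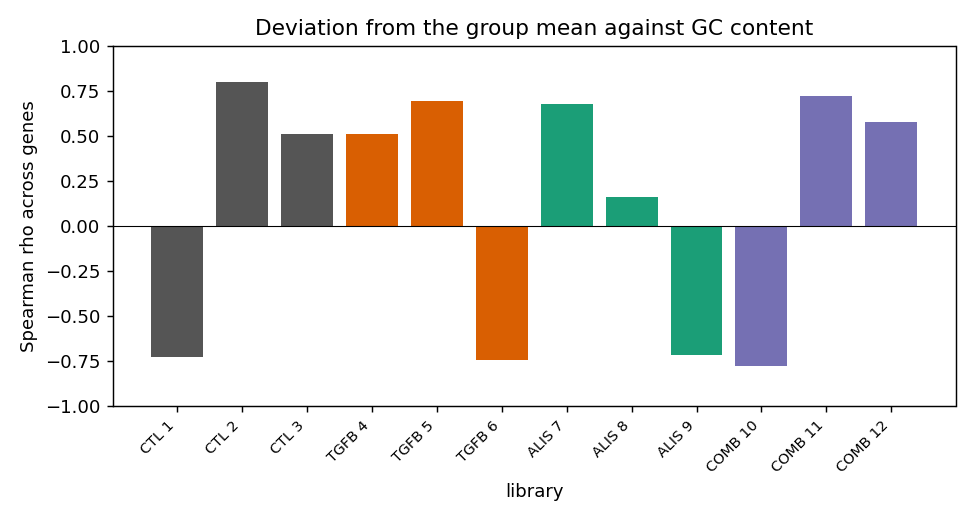
Spearman rho across genes between GC content and a library's deviation from its group mean, 1 bar per library, coloured by group (CTL untreated, TGFB TGFβ, ALIS alisertib, COMB both). The values were -0.78 to -0.717 in 4 libraries, 1 per group, and 0.158 to 0.801 in the other 8.

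TGFβ changed 7940 of 20571 genes in cells without alisertib, 3796 higher and 4144 lower, and 1128 and 1113 of these by at least 2-fold. The larger direction turned with DESeq2 (4005 higher and 3972 lower) and with an offset for GC content and length added after the data were seen (5008 and 4466). PMEPA1, a feedback inhibitor of TGFβ signalling, rose from 82.8 ± 2.95 to 1098 ± 13.5 CPM (SD, n = 3), a 13.3-fold change. FAP, a serine protease of activated fibroblasts, rose 117-fold from 0.294 ± 0.0815 to 34.3 ± 3.14 CPM. CIITA, the master regulator of MHC class II genes, fell from 28.9 ± 4.09 to 0.94 ± 0.0128 CPM. Its log2 fold change was -4.94 ± 0.18 (SE), with an edgeR quasi-likelihood adjusted p of 2.53e-11 after Benjamini-Hochberg adjustment, and its locus overlaps DEXI. In hg19, PMEPA1 (ENSG00000124225) lies on chromosome 20 from 56223448 to 56286592, FAP (ENSG00000078098) on chromosome 2 from 163027194 to 163101661 and CIITA (ENSG00000179583) on chromosome 16 from 10971055 to 11026079.

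Of 22 tested SMAD target genes, 19 rose, 1 fell and 2 did not pass, with the same 19 and 1 when adjusted over the list alone (camera adjusted p = 7.9e-49). PMEPA1 and SMAD7, feedback inhibitors of the pathway, rose by 3.73 ± 0.07 and 2.24 ± 0.06 on the log2 scale, and the secreted matrix protein TGFBI rose by 3.14 ± 0.05. Components of the pathway itself went both ways, with 6 higher, 8 lower and 11 not past, and 6 and 9 when adjusted over the list alone. BMP4 had a log2 fold change of -2.77 ± 0.07 and TGFB2, a TGFβ ligand, of -1.41 ± 0.05. That list was called lower at an adjusted p of 0.0435, against an adjusted p = 0.171 with an estimated correlation, and it was 0.0602 without TGFβ library 4, 0.0669 without TGFβ library 5 and 0.131 without a filter on low counts. In settings added after the data were seen, it was 0.116 with the GC and length offset and 0.0668 with the component covariate. Targets of BMP signalling fell in 6 of 9 cases and rose in 1, also when adjusted over the list alone (adjusted p = 0.00829, and adjusted p = 0.349 with an estimated correlation). ID1 and ID2, inhibitors of basic helix-loop-helix factors, had log2 fold changes of -1.94 ± 0.12 and -1.33 ± 0.11.

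Among 5 tested transcription factors of epithelial-mesenchymal transition, SNAI1, SNAI2 and ZEB1 rose, FOXC1 fell and 1 did not pass, and the counts were equal when adjusted over the list alone. SNAI1 rose from 0.811 ± 0.278 to 10.1 ± 1.2 CPM, and ZEB1 by 0.31 ± 0.05 on the log2 scale. The list passed at an adjusted p of 0.0443, against an adjusted p = 0.197 with an estimated correlation, and was not called without untreated library 2 (adjusted p = 0.075) or TGFβ library 6 (adjusted p = 0.0564) or without a filter on low counts (adjusted p = 0.0872). Of 14 mesenchymal markers, 10 rose, 3 fell and 1 did not pass, with 10 and 3 when adjusted over the list alone (adjusted p = 4.51e-14). FN1, the matrix glycoprotein fibronectin, rose 7.03-fold and the intermediate filament gene VIM rose 1.66-fold (1230 ± 5.85 to 2036 ± 32.7 CPM). Epithelial markers divided, with 7 higher, 8 lower and 3 not past, the same when adjusted over the list alone (adjusted p = 0.539). CDH1, which encodes E-cadherin, fell from 5.55 ± 0.374 to 1.81 ± 0.227 CPM.

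Extracellular matrix genes rose in 21 of 30 cases and fell in 4, also when adjusted over the list alone (adjusted p = 1.1e-20). COL6A3 rose by 3.38 ± 0.07, while COL12A1 had a log2 fold change of -2.44 ± 0.07. Proteases and their inhibitors rose in 11 of 17 cases and fell in 2, with 12 and 3 when adjusted over the list alone (adjusted p = 7.45e-19). The gelatinase MMP9, the metalloprotease ADAM19 and the urokinase gene PLAU rose 31.9-fold, 11.4-fold and 5.53-fold. Integrin subunits were higher in 7 of 14 cases and lower in 3, also when adjusted over the list alone (adjusted p = 4.17e-06), and ITGAV rose 3.13-fold. Genes of the contractile actin system were higher in 12 of 16 cases and lower in 3, with the same counts adjusted over the list alone. Their adjusted p was 1.08e-05, against an adjusted p = 0.123 with an estimated correlation, and TPM1 rose 4.3-fold while MYLK, the myosin light chain kinase, had a log2 fold change of -1.61 ± 0.06. Targets of the coactivators YAP and TAZ were lower in 13 of 22 cases and higher in 4, with 13 and 5 when adjusted over the list alone (adjusted p = 9.35e-06), and ANKRD1 had a log2 fold change of -2.05 ± 0.07.

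Mitosis genes were lower in 29 of 35 cases with none higher, and in 30 when adjusted over the list alone. The median log2 fold change was -0.35, the adjusted p 5.99e-07, and adjusted p = 0.172 with an estimated correlation. AURKA, the target of alisertib (ENSG00000087586, chromosome 20 from 54944445 to 54967393), fell from 286.6 ± 27 to 175 ± 3.05 CPM. DNA replication genes were lower in 19 of 33 cases and higher in 1, with 20 and 1 when adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.387 with an estimated correlation). The transcription factor gene E2F2 had a log2 fold change of -0.94 ± 0.08. Cholesterol synthesis genes rose in 21 of 24 cases and fell in 1, with 21 and 3 when adjusted over the list alone (adjusted p = 3.99e-08). INSIG1, a sterol sensor, rose from 27.6 ± 1.37 to 85.5 ± 3.46 CPM, and HMGCS1, an early enzyme of the pathway, rose 1.98-fold.

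The remaining lists did not pass their test in this comparison. Counts higher and lower were 5 and 0 of 9 histone genes, 7 and 8 of 22 p53 targets, 6 and 7 of 19 apoptosis regulators, 8 and 11 of 24 NF-κB and secretory genes, and 8 and 13 of 30 interferon-stimulated genes. They were 10 and 5 of 23 hypoxia and glycolysis genes, 12 and 6 of 23 stress response genes, 13 and 3 of 22 lysosome and autophagy genes, 2 and 9 of 18 ribosome biogenesis genes, 2 and 11 of 25 respiratory chain genes, and 4 and 4 of 12 stemness markers. Adjusted over the list alone, these counts were 6 and 0, 8 and 8, 6 and 8, 9 and 11, 8 and 13, 12 and 5, 13 and 6, 14 and 4, 3 and 10, 3 and 11, and 4 and 4. CDKN1A, the cell cycle inhibitor p21, rose 4.12-fold. Median, mean and test differed in sign for apoptosis regulators (-0.04, 0.09, down), stemness markers (-0.01, -0.21, up) and NF-κB genes (0.01, 0.01, down). Hypoxia and glycolysis genes were called higher without untreated library 2 or 3 (adjusted p = 0.0491 and 0.0489) and without a filter on low counts (adjusted p = 0.00851), and with the GC and length offset (adjusted p = 0.0449). Without that filter histone, lysosome and respiratory chain genes were called too (adjusted p = 0.0125, 0.00217 and 0.0185). Fry, which does not compare a list with other genes, called more of these lists. Its adjusted p was 0.000111, 9.24e-05, 1.42e-06 and 5.91e-06 for histone genes, p53 targets, apoptosis regulators and interferon-stimulated genes. For hypoxia, stress response, lysosome, ribosome biogenesis and respiratory chain genes the fry value was 0.00867, 0.00445, 2.91e-06, 0.0251 and 0.0111. Across genes the fold changes of this comparison rose with GC content (Spearman rho 0.339).

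**Figure D3:**
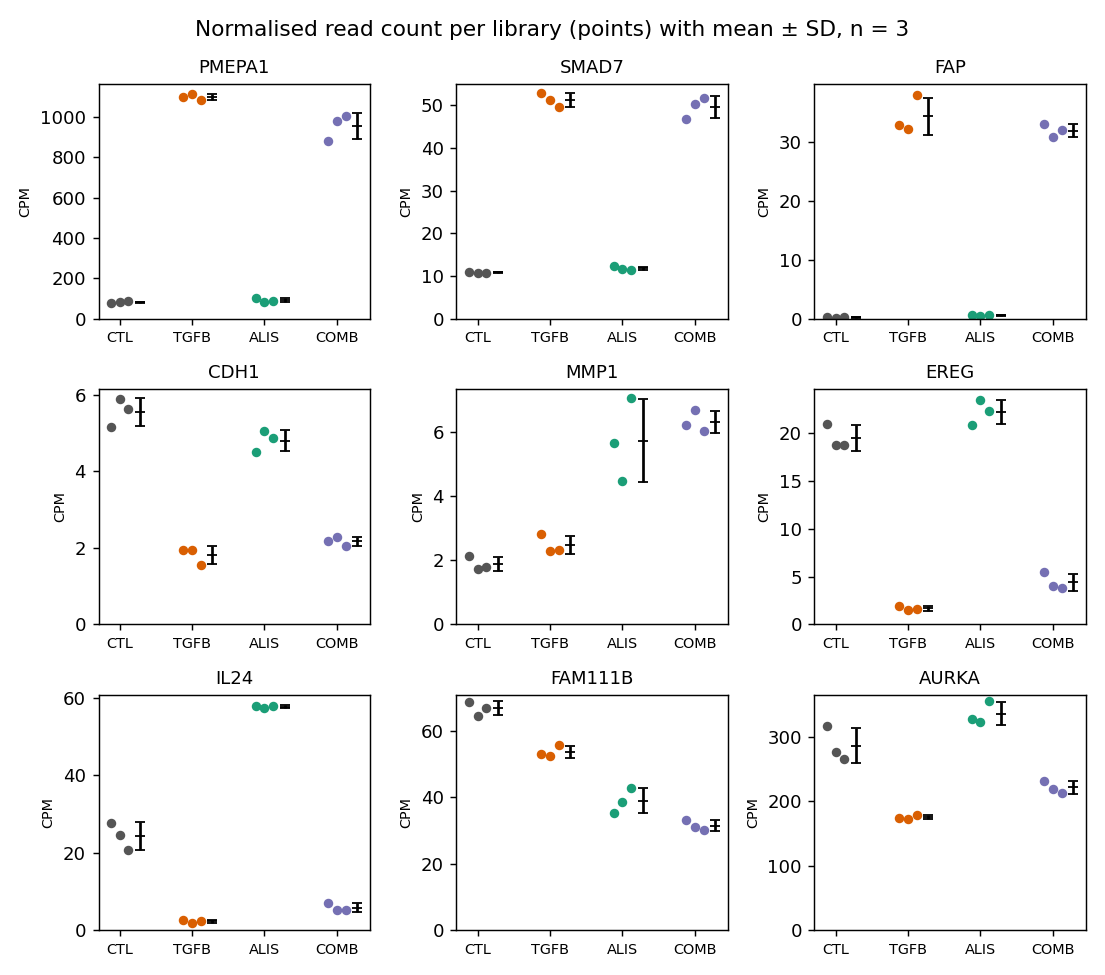
Normalised read count (CPM) of 9 genes in the 4 groups (CTL untreated, TGFB TGFβ, ALIS alisertib, COMB both); points are libraries and bars beside them the mean ± SD, n = 3. PMEPA1 lay at 82.8 CPM in untreated cells and 1098 with TGFβ, and MMP1 at 1.88 in untreated cells and 5.75 with alisertib.

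Alisertib alone changed 1387 genes, 730 higher and 657 lower, of which 106 and 25 changed by at least 2-fold. DNA replication genes fell and histone genes rose. The cytokine gene IL24 rose from 24.4 ± 3.58 to 57.8 ± 0.309 CPM (SD, n = 3), the carboxypeptidase gene CPA4 rose 2.14-fold and the collagenase gene MMP1 rose 3.06-fold. SCD, which encodes a fatty acid desaturase, fell from 150 ± 8.76 to 82.8 ± 2.97 CPM; its locus overlaps another counted gene. AURKA lay at 336.3 ± 17.9 CPM against 286.6 ± 27, a log2 fold change of 0.23 ± 0.06 (adjusted p = 0.0431). That call was lost in 9 of the 12 fits that left out 1 library, with the highest adjusted p of 0.137 without alisertib library 9.

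Of 33 DNA replication genes 20 fell and none rose, and 26 fell when adjusted over the list alone (median log2 fold change -0.32, adjusted p = 2.94e-25). The helicase subunit MCM6, the loading factor CDC45 and the nucleotide synthesis gene TYMS had log2 fold changes of -0.55 ± 0.07, -0.43 ± 0.06 and -0.39 ± 0.05; the TYMS locus overlaps another counted gene. Of 9 histone genes 7 rose and none fell, and 8 rose when adjusted over the list alone (median 0.66, adjusted p = 1.77e-14). HIST1H2AC rose from 11.3 ± 0.398 to 18.3 ± 0.374 CPM; histone genes have near-identical copies, so counts of single members are uncertain. Cholesterol synthesis genes fell in 9 of 24 cases with none higher, and in 12 when adjusted over the list alone (median -0.21, adjusted p = 1.83e-08). INSIG1 and STARD4, a sterol carrier gene, had log2 fold changes of -0.50 ± 0.05 and -0.38 ± 0.05.

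Proteases and inhibitors were higher in 6 of 17 cases and lower in none, with 8 and 0 when adjusted over the list alone (adjusted p = 3.55e-09). NF-κB and secretory genes were higher in 6 of 24 cases and lower in 1, with 6 and 2 when adjusted over the list alone (adjusted p = 0.000612). The interleukin genes IL1B and IL1A rose 1.93-fold and 1.88-fold and CSF3, a granulocyte growth factor gene, 2.05-fold. ADAMTS6, a metalloprotease gene of the protease list, rose 1.71-fold. SMAD target genes were higher in 7 of 22 cases and lower in 1, with 10 and 3 when adjusted over the list alone (adjusted p = 0.000136, and adjusted p = 0.0951 with an estimated correlation). KLF10 rose by 0.44 ± 0.05 and IL11 by 0.55 ± 0.06 on the log2 scale. BMP targets were lower in 3 of 9 cases and higher in none, with 4 and 1 when adjusted over the list alone (adjusted p = 0.00167, and adjusted p = 0.244 with an estimated correlation). Stemness markers were higher in 5 of 12 cases and lower in none, with 6 and 1 when adjusted over the list alone (adjusted p = 0.0057, and adjusted p = 0.0828 with an estimated correlation). CD24, ALDH1A1, SOX2, NANOG, PROM1 and LIN28B of the stemness list were not tested and are named for that reason only. KLF4, a transcription factor among the tested stemness markers, rose 1.39-fold, and ID2, a BMP target, had a log2 fold change of -0.78 ± 0.11.

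Mitosis genes did not pass as a list, with 4 higher, 0 lower and 31 not past, and 5 and 1 when adjusted over the list alone (median 0.03, adjusted p = 0.186). The list was called higher without untreated library 1 (adjusted p = 0.00621, 12 higher and 1 lower) and without alisertib library 8 (adjusted p = 0.0449). Weaker calls were made for interferon-stimulated genes (6 higher, 1 lower of 30, adjusted p = 0.0102), epithelial-mesenchymal transcription factors (1 higher of 5, adjusted p = 0.00866), p53 targets (3 higher, 1 lower of 22, adjusted p = 0.0365), lysosome and autophagy genes (4 higher of 22, adjusted p = 0.0365) and hypoxia and glycolysis genes (1 higher, 1 lower of 23, adjusted p = 0.0323). Adjusted over the list alone their counts higher and lower were 9 and 1, 3 and 0, 6 and 1, 7 and 1, and 1 and 2. None of these calls held with an estimated correlation: in the same order, adjusted p = 0.0504, 0.0951, 0.0951, 0.0991 and 0.571 with an estimated correlation. The p53 targets had a median of 0 and the test pointed up. Without untreated library 1 the adjusted p was 0.0661 for p53 targets and 0.0661 for lysosome genes, and without alisertib library 7 it was 0.101 and 0.072; for p53 targets it was 0.0569 without a filter on low counts. For hypoxia genes it was 0.17, 0.196, 0.123 and 0.0615 without untreated library 2, untreated library 3, alisertib library 7 and alisertib library 9, and 0.241 by fry. GADD45A, a stress-induced gene among them, rose from 18.1 ± 1.46 to 32.8 ± 0.671 CPM, and the apoptosis gene PMAIP1 rose 1.35-fold.

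The other lists did not pass with alisertib alone. Counts higher and lower were 0 and 3 of 25 TGFβ pathway parts, 2 and 1 of 14 mesenchymal markers, 0 and 2 of 18 epithelial markers, 3 and 0 of 30 extracellular matrix genes, 2 and 1 of 14 integrins, 2 and 1 of 22 YAP and TAZ targets, and 2 and 3 of 23 stress response genes. They were 1 and 0 of 16 actin genes, 1 and 2 of 19 apoptosis regulators, 0 and 0 of 18 ribosome biogenesis genes and 0 and 0 of 25 respiratory chain genes. Adjusted over the list alone they were 2 and 4, 5 and 3, 0 and 2, 4 and 1, 2 and 1, 2 and 1, 2 and 6, 1 and 0, 2 and 2, 0 and 0, and 0 and 0. Without untreated library 1 the lists of epithelial markers, ribosome biogenesis and the respiratory chain were called (adjusted p = 0.0105, 0.00701 and 0.0428). Without alisertib library 8 epithelial markers and ribosome biogenesis were called (adjusted p = 0.0449 and 0.0204). With the GC and length offset ribosome biogenesis and stress response genes were called (adjusted p = 0.0204 and 0.0494), and ribosome biogenesis also without a filter on low counts (adjusted p = 0.0384). Fry called TGFβ pathway parts, YAP and TAZ targets and apoptosis regulators (adjusted p = 0.0269, 0.0344 and 0.00296). CDH11, a cadherin of mesenchymal cells, had a log2 fold change of -0.37 ± 0.04 and BMP4 of -0.35 ± 0.06, while COL6A3 rose by 0.36 ± 0.06. Among stress response genes DDIT4, an inhibitor of mTOR signalling, fell from 224.9 ± 22.1 to 159 ± 5.88 CPM. Median, mean and test differed in sign for extracellular matrix genes (-0.08, 0.01, up), actin genes (-0.02, 0.13, up), leukocyte markers (0.13, -0.01, up) and luminal markers (-0.03, 0.05, down).

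The count of 1387 was 623 when only untreated and alisertib libraries were fitted, and without 1 library it was 2598 (untreated 1), 836 (untreated 2), 731 (untreated 3), 718 (alisertib 7), 723 (alisertib 8) or 823 (alisertib 9). With upper-quartile factors 769 genes were higher and 455 lower, 62.8% higher against 52.6%, with the GC and length offset 1499 were higher and 1829 lower, and the fold changes of this comparison fell with GC content (Spearman rho -0.173).

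**Figure D4:**
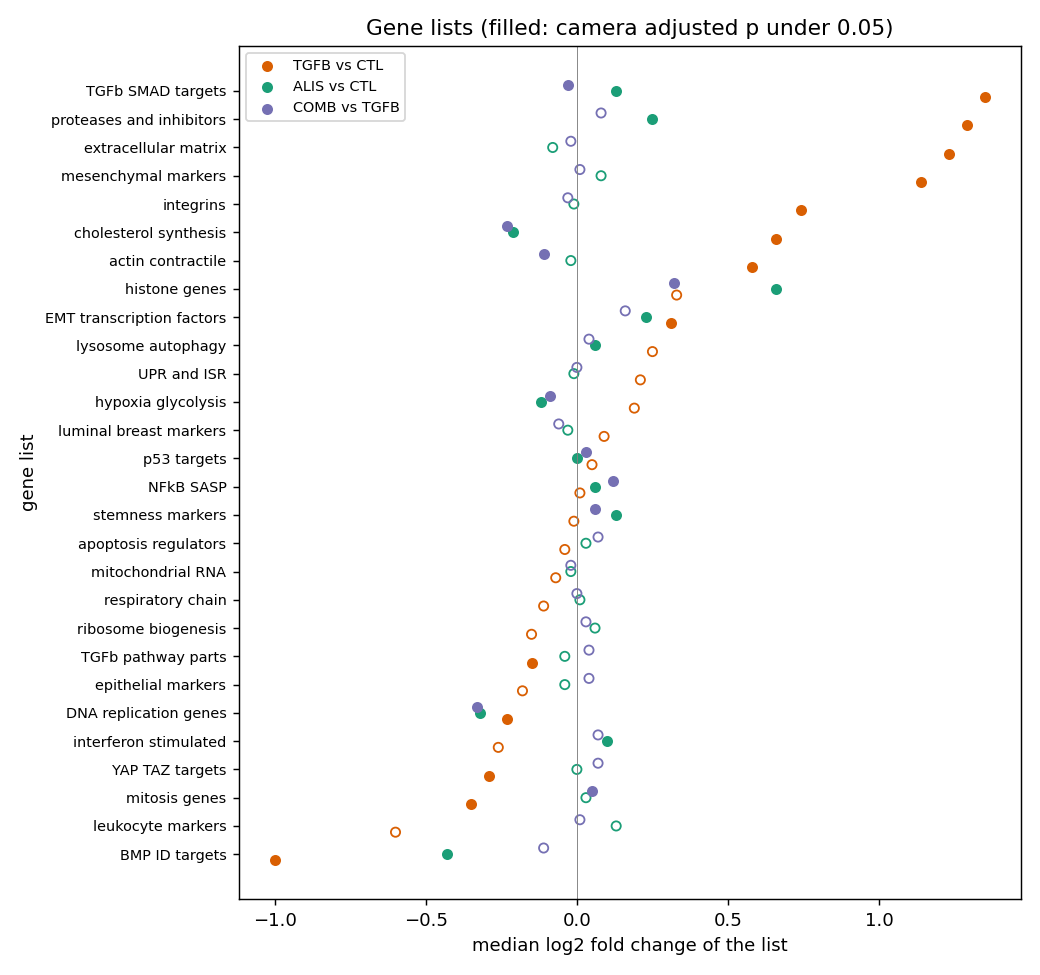
Median log2 fold change of 28 gene lists in 3 comparisons (TGFB vs CTL, TGFβ against untreated; ALIS vs CTL, alisertib against untreated; COMB vs TGFB, both against TGFβ); 1 point per list and comparison, filled where the camera adjusted p was under 0.05. DNA replication genes lay at -0.23, -0.32 and -0.33.

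Both agents together changed 8169 genes against untreated cells, 3983 higher and 4186 lower, and 1234 and 995 of these by at least 2-fold. The larger direction turned with DESeq2 (4158 higher and 4022 lower), with its size factors (4084 and 4030), with the GC and length offset (5124 and 4666) and without combined library 10 (4042 and 4008). PMEPA1 rose to 956.2 ± 65.4 CPM (SD, n = 3) and SNAI1 rose 12.5-fold, and CDH1 fell to 2.17 ± 0.117 CPM. DNA replication genes were lower in 28 of 33 cases with none higher, and in 29 when adjusted over the list alone (median -0.55, adjusted p = 5.52e-12). MCM6 had a log2 fold change of -1.08 ± 0.07 and E2F2 of -1.48 ± 0.08. Histone genes rose in 8 of 9 cases, also when adjusted over the list alone (adjusted p = 0.00253, and adjusted p = 0.0719 with an estimated correlation). SMAD targets rose in 18 of 22 cases and fell in 1, with 18 and 2 when adjusted over the list alone (adjusted p = 1.77e-45), and cholesterol synthesis genes rose in 19 of 24 cases and fell in 2, with 19 and 3 when adjusted over the list alone (adjusted p = 0.00263). ANGPTL4, a secreted regulator of lipoprotein lipase that either agent alone raised, rose 9.39-fold.

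Alisertib in the presence of TGFβ changed 428 genes, 245 higher and 183 lower, of which 27 and 5 changed by at least 2-fold. The growth factor gene EREG rose from 1.67 ± 0.238 to 4.4 ± 0.913 CPM (SD, n = 3), IL24 and MMP1 each rose 2.55-fold, and PDK4, a kinase that inhibits pyruvate dehydrogenase, rose 2.31-fold. The amino acid transporter gene SLC1A4 and FAM111B, which encodes a protease, had log2 fold changes of -0.78 ± 0.07 and -0.77 ± 0.07 (adjusted p = 0.000162 for both). WDR76 had a value of -0.62 ± 0.09 and CYP1A1, a cytochrome P450 gene, rose 1.73-fold. DNA replication genes fell in 19 of 33 cases with none higher, and in 29 when adjusted over the list alone (median -0.33, adjusted p = 3.19e-55). MCM3 fell from 395.1 ± 8.31 to 313.3 ± 7.54 CPM, and FEN1, a flap endonuclease whose locus overlaps other counted genes, had a log2 fold change of -0.36 ± 0.04. TYMS had a value of -0.43 ± 0.05. Cholesterol synthesis genes fell in 9 of 24 cases with none higher, and in 14 when adjusted over the list alone (median -0.23, adjusted p = 6.44e-21). HMGCS1 fell from 91.1 ± 3.77 to 65.8 ± 2.1 CPM, and INSIG1 had a log2 fold change of -0.42 ± 0.05.

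Histone genes rose in 3 of 9 cases and none fell, and 5 rose when adjusted over the list alone (median 0.32, adjusted p = 1.55e-09), with HIST1H2AC and HIST1H2BC 1.55-fold and 1.69-fold higher. NF-κB and secretory genes were higher in 4 of 24 cases with none lower, and in 8 with 1 lower when adjusted over the list alone (adjusted p = 0.000598), among them IL1B, which rose 1.88-fold. SMAD targets were lower in 3 of 22 cases, 4 when adjusted over the list alone, with none higher (adjusted p = 0.0246, and adjusted p = 0.392 with an estimated correlation). The matricellular gene THBS1 had a log2 fold change of -0.32 ± 0.04, whereas SMAD7 had a value of -0.05 ± 0.05 (adjusted p = 0.819). Without TGFβ library 5 or combined library 10 the SMAD target call was lost (adjusted p = 0.0585 and 0.224), as it was by fry (adjusted p = 0.127). AURKA rose by 0.34 ± 0.06 on the log2 scale, with an adjusted p of 0.0121. That call was lost in 3 of 12 fits without 1 library, without TGFβ library 4, TGFβ library 5 or combined library 10, with the highest adjusted p of 0.0688 without TGFβ library 4. The mitosis list was called higher with 2 of 35 members higher and 5 when adjusted over the list alone (adjusted p = 0.0246, and adjusted p = 0.543 with an estimated correlation).

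The p53 list was called higher in the presence of TGFβ with 2 of 22 members higher, the same count adjusted over the list alone (adjusted p = 0.0268, and adjusted p = 0.12 with an estimated correlation); GADD45A rose by 0.45 ± 0.06 on the log2 scale. Stemness markers were called with 1 of 12 higher, also when adjusted over the list alone (adjusted p = 0.0268, and adjusted p = 0.186 with an estimated correlation). Actin genes and hypoxia genes were called lower as lists with no single member past the test and medians of -0.11 and -0.09. Their adjusted p-values were 0.0246 and 0.0052, and adjusted p = 0.417 and 0.519 with an estimated correlation; adjusted over the list alone no actin gene passed, and 1 hypoxia gene was higher and 1 lower. By fry the adjusted p was 0.187, 0.24 and 0.3 for the mitosis, actin and hypoxia lists. Without TGFβ library 5 the adjusted p of the mitosis, p53, stemness, actin and hypoxia lists was 0.0612, 0.0612, 0.0585, 0.173 and 0.0585. Without combined library 10 it was 0.174, 0.0886, 0.268 and 0.0782 for the mitosis, stemness, actin and hypoxia lists, and without combined library 12 it was 0.0694 for p53 targets and 0.157 for stemness markers, which also lost the call without TGFβ library 4 (0.0783). Proteases and inhibitors did not pass, with 2 of 17 higher and none lower, and 3 and 0 when adjusted over the list alone (adjusted p = 0.058); the list was called in 5 of the 12 fits without 1 library, at the lowest without combined library 10 (adjusted p = 0.028), and with the GC and length offset (adjusted p = 0.033).

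Without 1 library the count of 428 was 754 (untreated 1), 153 (TGFβ 4), 180 (TGFβ 5), 232 (TGFβ 6), 243 (combined 10), 211 (combined 11) or 226 (combined 12). DESeq2 called 692 genes. The larger direction turned with only the groups compared (140 higher and 167 lower) and with the GC and length offset added after the data were seen, which called 1531 genes (746 and 785), and the fold changes fell with GC content (Spearman rho -0.229).

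TGFβ in the presence of alisertib changed 7901 genes, 3998 higher and 3903 lower, and 1016 and 942 of these by at least 2-fold. The balance depended on the processing, with 3230 higher and 4719 lower under upper-quartile factors (40.6% higher against 50.6%), 3314 and 3751 without a filter on low counts, 3273 and 3904 with the 1 CPM filter and 3941 and 3947 with limma-voom. Lower genes were also more numerous without untreated library 2 (4068 against 3787) or 3 (4131 against 3666), alisertib library 7 (3588 against 3422), 8 (3407 against 3289) or 9 (3411 against 2993), or combined library 12 (3308 against 2931). FAP rose 51.8-fold, PMEPA1 10.4-fold and SMAD7 4.2-fold, with n = 3 in each group. IL24 fell from 57.8 ± 0.309 to 5.73 ± 1.17 CPM and AURKA from 336.3 ± 17.9 to 221.6 ± 9.4 CPM. SMAD targets rose in 19 of 22 cases and fell in 1, also when adjusted over the list alone (adjusted p = 2.49e-45). Mitosis genes fell in 29 of 35 cases with none higher, and in 31 when adjusted over the list alone (adjusted p = 1.26e-07, and adjusted p = 0.147 with an estimated correlation). Cholesterol synthesis genes rose in 20 of 24 cases and fell in 2, with 21 and 2 when adjusted over the list alone (adjusted p = 7.18e-08).

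Each effect was then compared between the absence and the presence of the other agent, in groups that share no library. Of the 1387 genes changed by alisertib alone, 1260 (90.8%) had the same sign with TGFβ present. Both alisertib comparisons called 294 genes, 289 of them in the same direction: 141 higher and 148 lower, against 8.69 and 5.84 for independent lists of these sizes. Among the 1387 genes the median size of the change was 0.4 on the log2 scale without TGFβ and 0.2 in the same direction with it; the first value is raised by the selection of the genes on it. Among the 428 genes changed with TGFβ present, the median was 0.39 with TGFβ and 0.35 in the same direction without it, and 398 (93%) had the same sign. For TGFβ, 7840 of 7940 genes (98.7%) had the same sign with alisertib present. Across all genes, which are not independent replicates, the fold changes without and with the other agent correlated at 0.296 for alisertib and 0.856 for TGFβ (Pearson), and at 0.411 and 0.791 (Spearman).

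**Figure D5:**
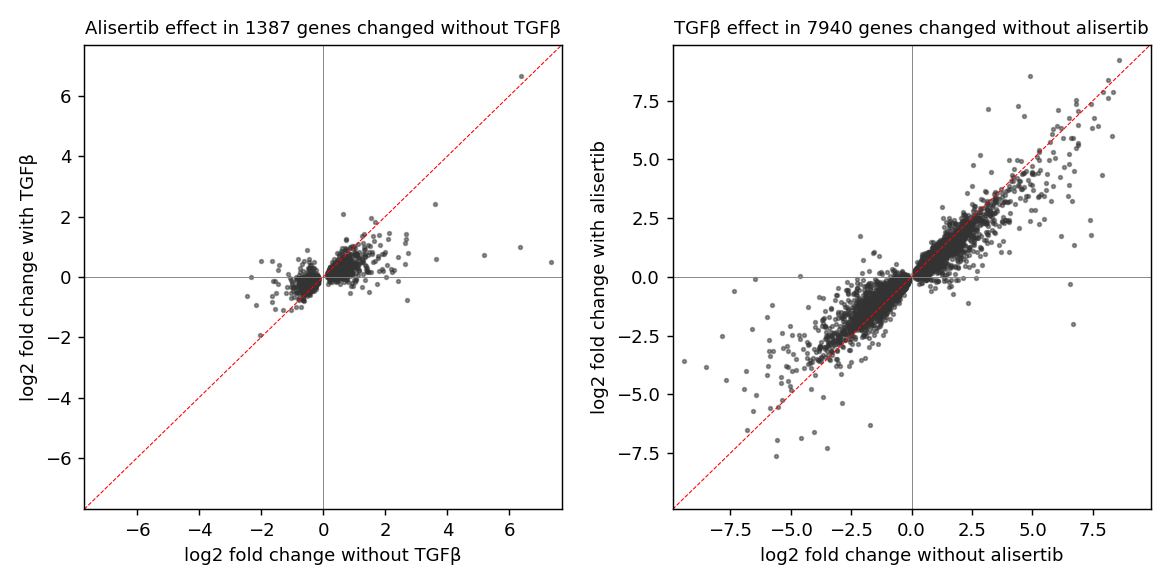
Log2 fold changes of single genes with the other agent present (vertical axis) against those without it (horizontal axis), for 1387 genes changed by alisertib and 7940 changed by TGFβ; each point is a gene and the dashed line marks equal change. The same sign was found in 90.8% and 98.7% of them.

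In 191 genes, named moved back below, the calls in TGFβ against untreated cells and in both agents against TGFβ had opposite directions. Of these, 40 were higher in the first comparison and lower in the second, and 151 were lower in the first and higher in the second. These comparisons show no order of treatment. Another 136 genes were called in the same direction in both. Independent lists of these sizes would give 33.8 and 49.4 of the first and second kind, and 82.1 in the same direction. The excess thus lay mainly in the 151 genes and was also found in the same direction, so it was not specific to opposite calls. In 20 simulated sets of unchanged groups the count was 0, which is no benchmark, since groups without effects leave nothing to be called in both comparisons. Both comparisons use the 3 TGFβ libraries, too few to split into parts of at least 2, so part of the excess can come from these shared libraries. Over 11306 genes with a mean of at least 5 CPM the covariance of the fold changes was -0.0150, against -0.00523 in the simulation, a difference of -0.00982. The simulation drew genes independently, without the deviation along GC content that libraries shared. Fold changes followed GC content in opposite directions in the first and second comparison (Spearman rho 0.339 and -0.229). The difference therefore cannot separate effects of the agents from that trend. INSIG1 and HMGCS1 were among the genes higher with TGFβ and lower with both agents than with TGFβ alone. EREG, IL24 and PDK4 were among those with the opposite pattern. Without 1 library the count was 300 (untreated 1), 74 (TGFβ 4), 80 (TGFβ 5), 112 (TGFβ 6), 97 (combined 10), 108 (combined 11) or 121 (combined 12).

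The response to alisertib differed with TGFβ status in 58 genes by the interaction test, 24 higher and 34 lower. PDE4B, a cyclic AMP phosphodiesterase gene, had the interaction value 0.96 ± 0.12 (adjusted p = 0.00674): it lay at 16.2 ± 0.964 CPM in untreated cells and 11.7 ± 0.604 with alisertib, and at 1.34 ± 0.0943 with TGFβ and 1.89 ± 0.112 with both (SD, n = 3). For EREG the value was 1.21 ± 0.18 and for the glutamate transporter gene SLC1A3 0.86 ± 0.14, and for CNKSR3 0.81 ± 0.14. Lower values were found for FAP (-1.17 ± 0.2), ADAMTS6 (-0.86 ± 0.1), MYH16 (-0.82 ± 0.12) and PTPRR (-0.79 ± 0.13). The level of FAP in untreated cells, given above for TGFβ alone, was very low, and its interaction value depends on that level. ADAMTS6, a metalloprotease gene, rose with alisertib from 22.2 ± 2.57 to 38 ± 0.988 CPM without TGFβ and lay at 102 ± 4.24 and 95.6 ± 1.03 CPM with it. SMAD targets had a median interaction of -0.18 with 3 lower and 19 not past, and 9 lower and 1 higher when adjusted over the list alone (adjusted p = 6.1e-13, and adjusted p = 0.0468 with an estimated correlation). DNA replication and cholesterol synthesis genes did not pass the interaction test as lists (medians -0.05 and -0.08, adjusted p = 0.0814 and 0.159). The DNA replication list was called lower without untreated library 1, alisertib library 8 or combined library 10 (adjusted p = 0.00616, 0.0181 and 0.0408) and without a filter on low counts (0.0404), against an adjusted p = 0.586 with an estimated correlation. Cholesterol synthesis was called lower with an offset for GC content and length added after the data were seen (adjusted p = 0.0451), against an adjusted p = 0.355 with an estimated correlation.

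Without 1 library the interaction count was 166 (untreated 1), 28 (untreated 2), 32 (untreated 3), 20 (TGFβ 4), 20 (TGFβ 5), 24 (TGFβ 6), 20 (alisertib 7), 30 (alisertib 8), 19 (alisertib 9), 36 (combined 10), 23 (combined 11) or 37 (combined 12). Regroupings of the libraries did not settle whether chance gives as many genes as the 58. The calls of EREG, SLC1A3, CNKSR3, FAP and PTPRR were lost in 4, 8, 9, 9 and 8 of the 12 fits without 1 library. The highest adjusted p was 0.0607 for EREG and 0.0906 for SLC1A3 (both without alisertib library 7), 0.121 for CNKSR3 (without TGFβ library 4), 0.0985 for FAP (without alisertib library 9) and 0.0803 for PTPRR (without combined library 11).

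Markers of other cell types showed no common direction with TGFβ. Of 8 tested leukocyte markers 2 were higher and 3 lower (adjusted p = 0.59), with a median of -0.6 and a test that pointed up, and of 8 luminal breast markers 2 were higher and 2 lower (adjusted p = 0.579), with a median of 0.09, a mean of -0.06 and a test that pointed down; the counts were equal when adjusted over each list alone. CSF1R, a macrophage receptor gene, rose by 2.52 ± 0.14 on the log2 scale; its locus overlaps a pseudogene. With alisertib alone 1 leukocyte marker and 0 luminal markers were called (adjusted p = 0.478 and 0.849 for the lists), also when adjusted over each list alone. The marker was CD68, at 0.35 ± 0.09 (adjusted p = 0.0386), whose locus overlaps another counted gene. Its call was lost in 8 of the 12 fits without 1 library, with the highest adjusted p of 0.16 without alisertib library 7, and in 2 of 10 other settings, without a filter on low counts and with only the groups compared. The 13 mitochondrial transcripts had a median log2 fold change of -0.07 with TGFβ and -0.02 with alisertib, and the list passed in neither comparison (adjusted p = 0.57 and 0.909). With the GC and length offset it was called lower with alisertib (adjusted p = 0.00506), with 7 lower, none higher and a median of -0.10; with 8 libraries 4 were higher, none lower and the median 0.05 (adjusted p = 0.145). With both agents against untreated cells MT-ND6 and MT-CO1 were called, at -0.23 ± 0.08 and -0.17 ± 0.06, and no transcript passed when adjusted over the list alone; the calls were lost in 3 and 4 of the 12 fits without 1 library, with the highest adjusted p of 0.109 and 0.121 without untreated library 1.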

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

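For the libraries that deviated together, the tests of GC content and depth were chosen only after the result was seen, as were both sets of regroupings that keep TGFβ status. The alternatives with a GC offset were also chosen after the data were seen.

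The response to alisertib differed with TGFβ status in 58 genes by a test of the difference itself, the interaction. Single genes past that test included EREG (1.21), PDE4B (0.96), SLC1A3 (0.86), CNKSR3 (0.81), FAP (-1.17), ADAMTS6 (-0.86), MYH16 (-0.82) and PTPRR (-0.79), as log2 differences between the alisertib effects with and without TGFβ. In the 12 fits without 1 library the call was lost in 4 for EREG, 8 for SLC1A3, 9 for CNKSR3, 9 for FAP and 8 for PTPRR. The value of FAP depends on its very low level in untreated cells. By lists the difference had an adjusted p of 6.1e-13 for SMAD targets, 0.0283 for TGFβ pathway parts, 0.019 for BMP targets, 5.85e-07 for proteases, 0.0177 for actin genes and 0.00223 for histone genes. With an estimated correlation these values were 0.0468, 0.216, 0.383, 0.0715, 0.373 and 0.151. The test pointed up for pathway parts and BMP targets, and down for SMAD targets, proteases, actin genes and histone genes. Few members passed: with the GC and length offset 3 pathway parts and 1 BMP target were higher. With it 7 SMAD targets, 5 proteases, 1 actin gene and 0 histone genes were lower. The median of the actin genes was 0.04 without untreated library 1. By fry the adjusted p was 0.336, 0.0656, 0.43 and 0.0656 for BMP targets, proteases, actin genes and histone genes, and with 8 libraries 0.277 and 0.0935 for the last pair. Of the 12 fits without 1 library the call was lost in 7 for pathway parts, 3 for BMP targets, 3 for actin genes and 1 for histone genes, with the highest adjusted p of 0.0992 (without combined library 10), 0.108 (without untreated library 2), 0.206 and 0.0684 (both without untreated library 1).

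Whether chance explains the counts was tested by regrouping libraries. For each pairwise comparison the real split was the 1 of 10 splits with as many genes, and the highest other count was 0, against 7940, 1387, 8169, 428 and 7901; 10 splits are too few for a share under 0.05. These counts are from edgeR alone; at an unadjusted p under 0.05 the highest other split had 1654, 4333, 2471, 1566 and 1994 genes, against 9536, 4070, 9683, 2639 and 9572. For alisertib alone, a split other than the real one thus gave more genes before adjustment. Every other split mixed libraries of the groups compared, so a treatment effect adds to the spread within groups and can lower the counts. For TGFβ alone the coefficient of variation was 21.4% to 22.16% in the other splits, against 9.4%. Their counts of 0 are therefore no benchmark for chance. Of 100 random regroupings of the 12 libraries 2 gave at least 58 interaction genes, the real one included, with 9416 in the highest other, a regrouping that set libraries without TGFβ against libraries with it and so follows the TGFβ effect. In these random regroupings 98 gave 0 genes. TGFβ was spread into their groups, with a median coefficient of variation of 26.95% against 9.4%, which can lower the counts. With TGFβ status kept 76 of 100 gave 0 genes as well, so that spread need not be the only reason. When TGFβ status was kept, 10 of 100 gave as many genes, the real one included, with 2453 in the highest other, but 8 of the 9 others carried the alisertib effect itself into the difference and decide nothing. In the 82 regroupings where that effect cancels, 2 gave as many, the real one included, with 1160 in the highest other. That regrouping gave untreated library 1, TGFβ library 6, alisertib library 9 and combined library 10 the same sign in the difference; its count points to a structure of the samples, but the other 7 of the 8 regroupings that did so gave 0 genes by edgeR, and 1403 to 4394 at an unadjusted p under 0.05. The other 81 mixed libraries with and without alisertib, with a median coefficient of variation of 11.35% against 9.4%, which can lower their counts, so whether chance gives 58 genes stays open. At an unadjusted p under 0.05, 11 of the 81 gave at least the 1170 of the real grouping. Of the 191 genes moved back, 2 of 100 random regroupings gave as many, the real one included, with 5430 in the highest other, which carries the same limit.

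Untreated library 1, TGFβ library 6, alisertib library 9 and combined library 10 deviated from their groups in the same genes. A shared component held 76.1% of the within-group variance, and 50.3% with an offset for GC content and length. A swap of untreated library 1 with alisertib library 9 is argued against by their positions of 0.13 and 0.99 on an axis from untreated (0) to alisertib (1) libraries. A candidate explanation is a GC-dependent bias, since gene weights on the component followed GC content with a Spearman rho of -0.803; depth stays open, as 3 of the 4 were the shallowest of their group and TGFβ library 6 the deepest. No biological explanation was tested.

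With alisertib, DNA replication and cholesterol synthesis genes were lower and histone genes higher. With the GC and length offset their medians were -0.29 (jackknife SE over libraries 0.03), -0.20 (SE 0.02) and 0.59 (SE 0.08), against -0.32, -0.21 and 0.66 as reported, which argues against GC and length trends as the whole cause. Without untreated library 1 they were -0.32 (SE 0.04), -0.25 (SE 0.02) and 0.62 (SE 0.06), which argues against that library as the cause. An effect of alisertib may account for the pattern, as a hypothesis found and tested on the same data. Other technical causes were not tested.

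SMAD targets were raised less by TGFβ when alisertib was present, with a median interaction of -0.18 (jackknife SE 0.04), from a higher start. Alisertib alone had raised 7 of the 22 genes and lowered 1 (list median 0.13, camera adjusted p = 0.000136, and adjusted p = 0.0951 with an estimated correlation). Against untreated cells the median was 1.35 with TGFβ and 1.41 with both agents and the mean 1.54 and 1.49, and both agents directly against TGFβ gave a median of -0.03 with 0 higher and 3 lower (adjusted p = 0.0246, and adjusted p = 0.392 with an estimated correlation). With the offset it was -0.20 (SE 0.03), which argues against GC and length trends as the whole cause. Without untreated library 1 it was -0.17 (SE 0.07), too wide to exclude that library. A ceiling for the genes raised most and an effect of alisertib on the TGFβ response both stay open. Across the 22 genes the interaction fell with the TGFβ effect in the presence of alisertib (Spearman rho -0.67, permutation p = 0.00102, genes not being independent replicates). That relation cannot tell them apart. A response weakened by alisertib in proportion to its size would also lower the interaction most in the genes raised most.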

How the results depend on the processing

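The GC and length offset, the fit of 8 libraries and the component covariate were chosen after seeing the data. Other alternatives were planned. The 8 libraries were selected for agreement and the covariate comes from the residuals it removes, so both make the spread too small; the offset can also remove real differences linked to GC content.

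Size factors of the DESeq2 kind and upper-quartile factors left all 7 counts within 1.5 times the reported one and both shares within their 95% binomial interval. That interval treats genes as independent, which they are not, so it is only a yardstick and not a spread between libraries. The balance of higher and lower genes moved more: with upper-quartile factors it was 3285 and 4712 for TGFβ (3796 and 4144 reported), 769 and 455 for alisertib (730 and 657) and 3230 and 4719 for TGFβ with alisertib (3998 and 3903). With the offset the larger direction turned for TGFβ (5008 and 4466), alisertib (1499 and 1829), both agents (5124 and 4666) and alisertib with TGFβ (746 and 785). Genes changed by alisertib alone (1387 reported) numbered 623 with only the groups compared, 3328 with the offset, 5073 with 8 libraries and 5324 with the covariate. Those changed by alisertib with TGFβ (428) numbered 692 with DESeq2, 1531 with the offset, 1434 with 8 libraries and 3181 with the covariate. Interaction genes (58) numbered 105 without a filter, 188 with DESeq2, 37 with limma-voom, 262 with the offset, 744 with 8 libraries and 699 with the covariate. Genes moved back (191) numbered 619, 569 and 1553 in the last 3 settings. The same-sign share for alisertib (90.8%) was 84.3% with 8 libraries and 89% with the covariate. For TGFβ (98.7%) it was 99.2% with the 1 CPM filter, 98.5% with the offset, 96.7% with 8 libraries and 97.8% with the covariate. The offset called 1352 of the 1387 genes and 55 of the 58, with the same sign in each. The extracellular matrix list, not called for the interaction (adjusted p = 0.171, down), was called lower without untreated library 3 (adjusted p = 0.0195) and with the offset (adjusted p = 0.0373). It was called in the other direction with 8 libraries (adjusted p = 0.0459). Fewer libraries were fitted in that setting, and otherwise the cause was not tested.

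Leaving out 1 library gave 6511 to 8018 genes for TGFβ, 718 to 2598 for alisertib, 6680 to 8114 for both, 153 to 754 for alisertib with TGFβ, 6239 to 8984 for TGFβ with alisertib, 19 to 166 for the interaction and 74 to 300 moved back. The shares ran from 89.24% to 93.06% and from 98.04% to 98.97%. Over all combinations of a list test and a left-out library, the call was lost in 45 and gained in 32 cases, and over those of a named gene test and a left-out library in 260 and 28. An estimated correlation ended 35 list calls. Fry, which does not compare a list with other genes, ended 9 and added 37. No paired analysis was possible because the groups share no replicate numbers.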

Other observations

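The gene group below was chosen after its values were seen. CIITA and other genes of MHC class II antigen presentation were lower with TGFβ in 13 of 13 tested cases, with log2 fold changes of -4.94 for CIITA itself and -4.10 to -0.39 for the other 12. HLA-DRA, an antigen-presenting chain, fell from 220.3 ± 1.81 to 19.8 ± 0.382 CPM (SD, n = 3), HLA-DMA, a peptide exchange factor, from 49.5 ± 3.62 to 6.47 ± 0.414 CPM and the invariant chain gene CD74 from 327.1 ± 52.4 to 100.7 ± 4.83 CPM. HLA genes have close paralogs that can share reads, so the values of single members are uncertain.

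Class I genes differed from this: HLA-B and HLA-C had log2 fold changes of -0.01 and 0.09 with TGFβ (adjusted p = 0.94 and 0.361), and B2M of -0.15 (adjusted p = 0.0296). With alisertib alone 4 of the 13 genes were lower and 1 higher, at -0.62 to 0.51 over the group. Interaction values ran from -0.5 to 0.52 in the 12 genes other than CIITA, which had 0.92, and none passed the test.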
